A study of Mus musculus with 2 samples.

How the data were processed

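Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, in forebrain of B6NCrl mouse embryos at embryonic day 15.5. Per the labels, the 2 biological replicates were pools of 78 and 62 embryos of both sexes, and they formed a single group. The pools are separate tissue samples of the same strain, so the spread between them holds both biological and technical differences.

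The deposited data were 4 peak lists on mouse genome build mm10. Per the text descriptions deposited beside them, each replicate's list was made from that replicate's own alignments together with 1 further input file, the pooled list from the alignments of both replicates, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, its version, its threshold and the rule by which a pooled peak entered the replicated list are not given in the sources used here. Each deposited peak carried a fold enrichment, a ratio taken from the signal column of the peak format; what it is relative to is not given in the sources used here. Each deposited peak also carried a −log10 p and a −log10 q as the authors' caller gave them, the lowest −log10 p being 2.03 and 2.04 in the replicates' lists. The deposited display score, a number for genome browsers, was not used in any comparison. The lists held no read counts, so the depth of each sample is unknown, and differences between the lists in number of peaks can come from depth. Fold enrichments are the authors' values for each peak. They were used to describe and rank peaks within a list and to compare the replicates with each other.

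Coordinates were kept as deposited and are given 1-based on mm10. The reference sequence and annotation (GENCODE mouse release 21) were of the same assembly: chromosome names matched, and 0 peaks ended past a chromosome end. The overlap between lists used all peaks. Comparisons with genes, random placements and sequence words used 21 chromosomes, 19 autosomes with X and Y, and left out the mitochondrial genome and unplaced or unlocalized sequences. Gene positions were those of 21938 protein-coding genes with 93513 distinct transcription start sites (TSSs).

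A peak was counted as shared with another list when an overlap covered at least 50% of either peak. Concordance of fold enrichment was described by Spearman's rho, and by Pearson's r on the log2 scale, over the replicate 1 peaks shared with replicate 2, each paired with its largest overlap. These are values across peaks, which are not independent replicates, so no p-value is given. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only. A promoter was the 1 kb on either side of a TSS of a protein-coding gene, and a gene was called marked when a peak overlapped any of its promoters. Peaks were assigned to promoters first, then to exons, introns and intergenic sequence. The replicated peaks were placed at random 100 times on their own chromosomes, outside assembly gaps of 100 bp or more, to give the distribution that their widths alone would give.

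A set of 23 gene lists with 429 entries, all of which matched the annotation, covered forebrain cell types, other cell types that the dissected tissue could hold, other brain regions, other organs and housekeeping genes. The lists came from general knowledge of these tissues and not from this study, and 6 genes stood in more than 1 list. Each list's share of marked genes was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. Genes are not independent replicates, and the test describes the replicated list; the counts were repeated in each replicate's own list. Distal peaks, those outside all promoters, were counted within 50 kb of each gene's TSSs, and the median per list was placed among 10000 random lists with the same number of marked and unmarked genes. Distal peaks at most 12.5 kb apart were joined into domains and ranked by the sum over peaks of fold enrichment times width. Sequence words were counted on both strands in 500 bp windows centred on distal peaks and in 500 bp windows 3 kb to either side that overlapped no pooled peak. The log2 ratio of their frequencies was reduced by the median over all words of the same length and base composition.

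The list test was checked on simulated data over all 21938 genes with lists of 16 and 22 genes. Made shares of 0%, 10% and 95% marked genes were called in 100%, 90.0% and 83.0% of changed lists, and under 1% of the unchanged lists were called, so a list test can miss a share of 95%. The overlap count and the word count were also checked on simulated data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

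The comparisons, the gene lists, the words, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were named by this rule: in each list, up to 4 marked genes with the largest fold enrichment at a promoter and up to 4 unmarked genes in alphabetical order; the nearest genes of the top 20 domains; the genes at the 10 strongest peaks; in each replicate, the 5 strongest peaks without a base in common with the other list; and the 10 genes with the widest promoter peaks. Of the genes the rule selected, the text gives those that carry each comparison. The alternatives were an overlap of 1 bp or of 50% of both peaks, a −log10 q of at least 2 or 5, lists cut to equal length by −log10 p, the 20000 peaks with the largest −log10 p, each replicate's own list, the pooled list, promoters of 0.5 or 2.5 kb, only the 5′ end of each gene, a distal window of 100 kb, a background without olfactory and vomeronasal receptor and predicted genes, joining at 5 kb, ranking by covered length, word windows at the summit and flanks 10 kb away. A pair of alternatives was chosen after seeing the data: distal domains defined against the TSSs of every annotated gene, non-coding genes included, and random lists drawn without the same receptor and predicted genes.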

Results

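H3K27ac was profiled by ChIP-seq in mouse forebrain at embryonic day 15.5, in 2 biological replicates made from pools of 78 embryos (replicate 1) and 62 embryos (replicate 2). Replicate 1 had 92800 peaks covering 56.9 Mb and replicate 2 had 85384 peaks covering 53.6 Mb. The pooled list held 102792 peaks and the replicated list 57064 peaks covering 60.7 Mb, or 2.23% of the genome. Read depth per sample was unknown. The labels name a single tissue, age and mark without a contrast, so the comparisons were those between replicates, between lists and between groups of genes or regions within the mark. Fold enrichments are the authors' values per peak; values given for a gene are those of its strongest promoter peak in the replicated list, with those of replicates 1 and 2 in their own lists beside them.

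The first comparison was between the replicates. Promoters of forebrain regulators were marked in both pools. Foxg1, the transcription factor that specifies telencephalon, had a promoter enrichment of 47.0 (44.5 in replicate 1 and 40.3 in replicate 2), and Bcl11b, a factor of subcortical projection neurons, had 42.0 (48.2 and 37.2). The strongest replicated peaks lay at the promoters of Zfp143 (chromosome 7, 110061671 to 110063539, enrichment 65.6), Klf7 (chromosome 1, 64115835 to 64123330, 65.2) and Kmt5b (chromosome 19, 3766631 to 3769376, 64.8). Rfx3, Nrf1, Dyrk1a, Epc1 and Myt1l promoters followed with 59.8 to 61.8. The other 2 of the 10 strongest peaks lay outside promoters of protein-coding genes. Their distances were 3628 bp to the nearest TSS of Sirt4 and 59397 bp to that of Mef2c, a transcription factor of neurons and muscle. TSSs of non-coding genes were not considered here. All 10 were found in both replicates, where the peak at Dyrk1a differed most, with 26.4 in replicate 1 and 56.0 in replicate 2.

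Of the replicate 1 peaks, 55358 (59.7%, interval 59.3 to 60.0) were shared with replicate 2, and 56233 of the replicate 2 peaks (65.9%, interval 65.5 to 66.2) were shared with replicate 1. Replicate 1 peaks placed at random shared 2.97% on average (range 2.81 to 3.09 over 100 placements). Over the 55358 shared pairs, fold enrichment had a Spearman's rho of 0.698 and a Pearson's r of 0.809, and 94.1% of pairs lay within 2-fold of each other. Sharing depended on enrichment. In the strongest decile, 99.97% of replicate 1 peaks and 100% of replicate 2 peaks were shared, while in the weakest decile 32.0% and 39.3% were shared. Unshared peaks had median enrichments of 3.02 and 2.94 and median widths of 233 and 237 bp in replicates 1 and 2, against 4.501 and 4.16 and 556 and 523 bp for shared peaks.

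The strongest replicate 1 peak with no base in common with the replicate 2 list lay 19332 bp from the nearest TSS of the neural adhesion gene Opcml (chromosome 9, 28680961 to 28681493, enrichment 7.77). The strongest such peak of replicate 2 lay 106485 bp from Dhx35 (chromosome 2, 158957114 to 158957599, enrichment 6.82). They ranked 12544 and 13431 in their lists, and the next 4 in each replicate, nearest to Rnft2, Dpp4, Cyth3 and Ank3 in replicate 1 and to Tbc1d4, Adpgk, Epha4 and Rps6kc1 in replicate 2, had enrichments of 6.18 to 7.10. The −log10 q of these peaks was 13.6 to 22.9. By gene, 11776 genes were marked in both replicates' own lists, 494 in replicate 1 only and 365 in replicate 2 only, and promoter enrichment had a Spearman's rho of 0.914 across genes, which are not independent replicates.

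**Figure D1:**
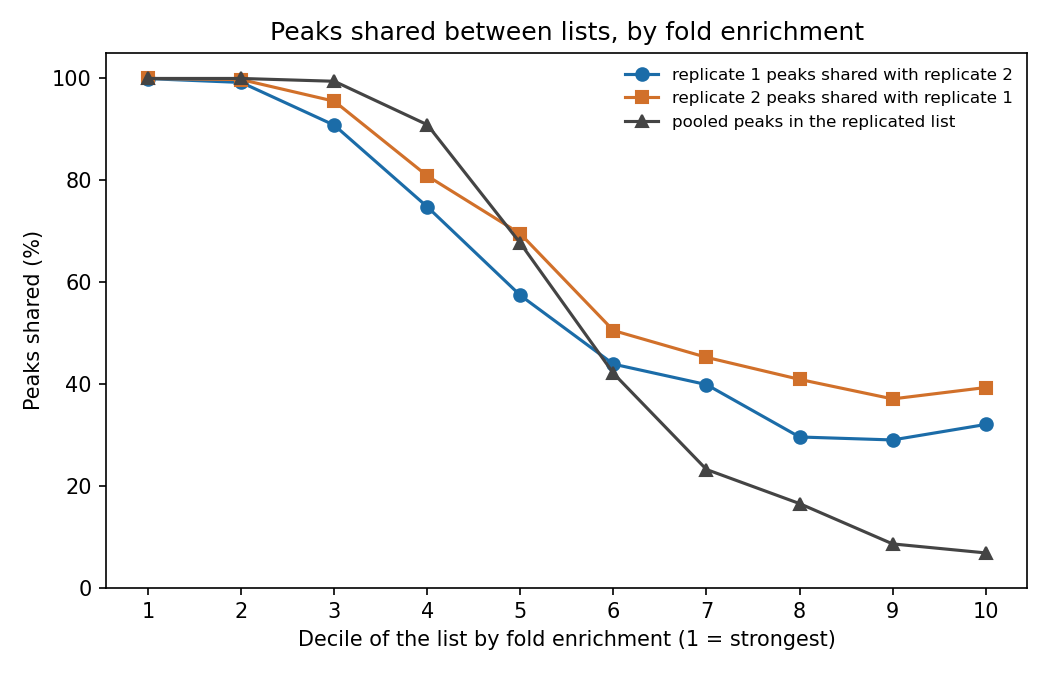
Share of peaks (%, vertical axis) found in the other list, by decile of each list ranked by fold enrichment (horizontal axis, 1 is the strongest decile); circles are replicate 1 peaks found in replicate 2, squares replicate 2 peaks found in replicate 1, and triangles pooled peaks present in the replicated list. The share fell from 100% of replicate 2 peaks in the strongest decile to 39.3% in the weakest, and from 100% to 6.81% for pooled peaks.

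The second comparison set the replicated list against the pooled list. All 57064 replicated peaks were peaks of the pooled list with identical coordinates and enrichment, and they made up 55.5% of it. Replicated peaks had a median enrichment of 4.20 and a median width of 742 bp, against 2.49 and 245 bp for the 45728 other pooled peaks. By promoter peaks, 12652 genes were marked in the pooled list and 11882 in the replicated list. Olig2, a gene of oligodendrocyte precursors, was marked in the replicated list (enrichment 2.56) and in neither replicate's own list. Of the pooled peaks, 50544 (49.2%) overlapped peaks of both replicates, and all of these were in the replicated list. Among replicated peaks, 3582 overlapped replicate 1 only, 2757 replicate 2 only and 181 neither list at the 50% overlap.

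The third comparison asked where the mark lay. Promoters of protein-coding genes held 15173 replicated peaks, or 26.6%, against 5.71% (range 5.50 to 5.93) in random placements, a 4.66-fold difference. Introns held 38.7% (random 34.3%), exons 2.54% (random 2.61%, range 2.48 to 2.77) and intergenic sequence 32.2% (random 57.4%). In the replicates' own lists, promoters held 21.8% ± 0.912 (SD, n = 2) and introns 42.5% ± 0.541 (SD, n = 2). By length, promoters took 28.6% of the marked sequence in the replicated list and 28.7% ± 0.724 (SD, n = 2) in the replicates' own lists. Promoter peaks had a median enrichment of 7.98 and a median width of 1101 bp, and distal peaks had 3.78 and 661 bp.

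**Figure D2:**
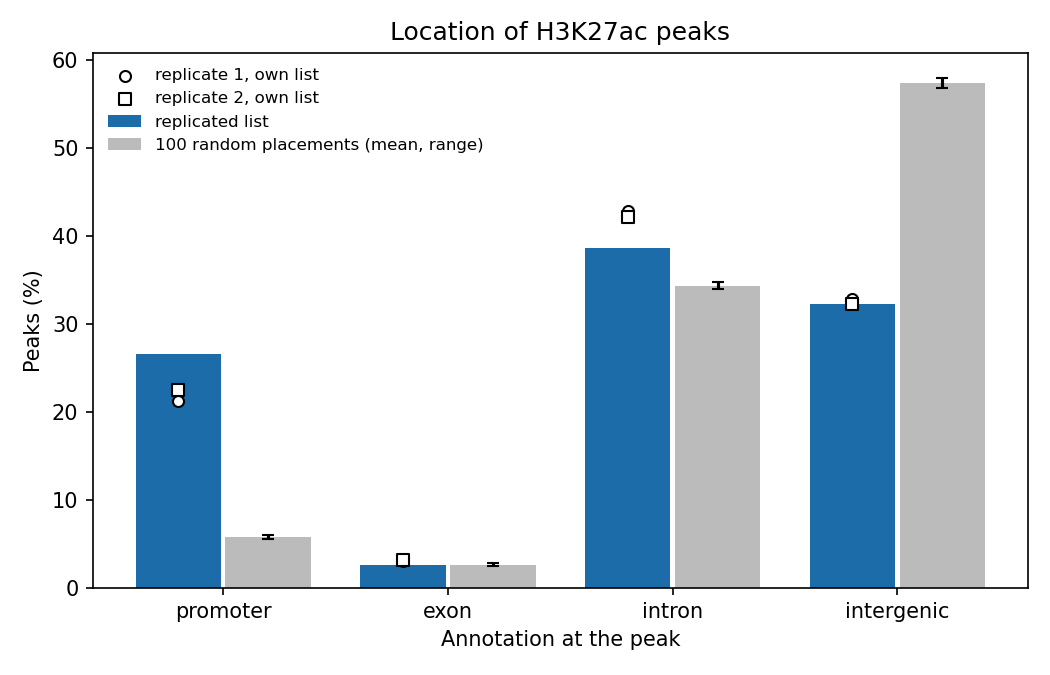
Share of peaks (%, vertical axis) at promoters, exons, introns and intergenic sequence (horizontal axis) in the replicated list (blue bars), in each replicate's own list (open circles and squares) and in 100 random placements of the replicated peaks (grey bars, mean with the range as error bars). Promoters held 26.6% of replicated peaks against 5.71% at random, and intergenic sequence 32.2% against 57.4%.

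The promoter peaks were also ranked by width. A peak of 38.1 kb covered the promoter of Nfix (chromosome 8, 84763691 to 84801837), a nuclear factor I gene of neural progenitors, and was called at 33315 bp in replicate 1 and 23302 bp in replicate 2. Meis2, a homeobox gene of the striatum, had a promoter peak of 22.5 kb (chromosome 2, 116055033 to 116077517), and Bcl11b one of 19.7 kb (chromosome 12, 107987617 to 108007275), called at 14906 and 5998 bp in the replicates. Pou3f3, Sox1, Mn1, Tnrc18, Lyl1, Neurod2 and Lhx2 completed the 10 widest, at 13.6 to 17.1 kb. All 10 were narrower in both replicates' own lists, in replicates 1 and 2 respectively Lyl1 with 4568 and 12180 bp, Neurod2 with 7562 and 13707 bp, Pou3f3 with 8540 and 17046 bp, Sox1 with 9847 and 7223 bp and Lhx2 with 7481 and 6830 bp. The peak at Lyl1 covered promoters of 2 genes and lay on chromosome 8 at 84701016 to 84715311, close to the Nfix peak.

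The fourth comparison asked which genes of regional and cell type lists were marked at promoters. In all, 11882 of 21938 protein-coding genes (54.2%) were marked, and 21 of the 23 lists differed from all other genes after adjustment by Fisher's exact test, 6 with a higher and 15 with a lower share. The 6 higher lists were those of cortical glutamatergic neurons, pan-neuronal genes, radial glia, intermediate progenitors, subpallial and GABAergic genes, and housekeeping genes. Microglial, erythroid, Hox and endoderm genes had no marked member. Marked share rose with the CpG content of promoters, measured around the 5′ end of each gene. It went from 2.92% of genes in the lowest of 20 equal bins to 95.1% in the highest.

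All 25 genes of cortical glutamatergic neurons were marked (adjusted p = 3.68e-06, Fisher's exact test), with a median enrichment of 22.8 against 11.4 over all marked genes. Medians of the other lists with a higher share ran from 12.3 (radial glia) to 18.9 (pan-neuronal), with housekeeping genes at 18.4. The largest values among the glutamatergic genes were those of Pou3f2 at 48.8 (46.5 and 41.8 in replicates 1 and 2), Pou3f3 at 43.4 (43.5 and 35.0), Sox11 at 43.1 (32.2 and 30.2) and Bcl11b. All 20 pan-neuronal genes were marked (adjusted p = 3.37e-05, Fisher's exact test), led by Myt1l, a repressor of non-neuronal genes, at 59.8 (57.3 and 39.6), then Map2 at 33.7 (29.9 and 29.8), Celf4 at 30.9 (26.0 and 27.6) and Mapt, the tau gene, at 26.8 (24.6 and 20.9). Both lists were fully marked in each replicate's own list.

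Of the radial glia and progenitor genes, 21 of 22 were marked (adjusted p = 0.0001, Fisher's exact test), among them Foxg1, Vim at 27.5 (27.3 and 21.3), Sox2 at 27.05 (18.9 and 26.4) and Sox1 at 25.7 (25.3 and 21.6). The exception was Tnc, the gene of the matrix protein tenascin-C, which had a peak of 4.52 in replicate 1 only. Intermediate progenitor and neurogenic genes were marked in 14 of 16 cases (adjusted p = 0.0131, Fisher's exact test), with Tcf4 at 44.8 (36.8 and 37.9), Insm1 at 37.1 (36.6 and 32.0), Tcf12 at 25.2 (21.5 and 19.5) and the Notch ligand gene Dll1 at 23.6 (21.01 and 19.02). Neurod4 and Neurog1, both proneural genes, had no promoter peak in the replicated list or in either replicate's list. Neurog1 had 5 distal peaks within 50 kb.

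Subpallial and GABAergic genes were marked in 23 of 28 cases (adjusted p = 0.00589, Fisher's exact test). Foxp1 had an enrichment of 51.0 (41.8 and 44.3), Meis2 36.5 (29.6 and 35.9), the GABA-synthesising enzyme gene Gad2 27.7 (26.7 and 24.1) and Dlx1, a homeobox gene of interneuron progenitors, 24.2 (23.6 and 24.4). The dopamine receptor genes Drd1 and Drd2, Gsx1, the neuropeptide gene Npy and, named after its values were seen, Sst were unmarked; Drd1 had 5 distal peaks within 50 kb. Random lists matched on promoter CpG content had 21.1 marked genes on average, with a central 95% of 17 to 25, so the count of 23 lay inside that range. Of the mature and activity-regulated neuronal genes, 11 of 16 were marked, which did not pass the threshold (adjusted p = 0.318, Fisher's exact test); Grin2b, an NMDA receptor subunit gene, had 19.6 (13.7 and 17.7), while Nptx2, Nrgn and Pvalb had no promoter peak in any of these lists. Housekeeping genes were marked in 19 of 20 cases (adjusted p = 0.000305, Fisher's exact test), led by Actb at 52.3 (50.4 and 42.1), and the unmarked gene was Gusb.

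Hox genes and regulators of midbrain, hindbrain and spinal cord were almost all unmarked, and so were most genes of the diencephalon list. None of the 39 Hox genes, which pattern hindbrain and spinal cord, had a promoter peak in the replicated list or in either replicate's list (adjusted p = 1.36e-12, Fisher's exact test). Hox genes lie close together, as Hoxa1, Hoxa10, Hoxa11 and Hoxa13 do on chromosome 6 (52155590 to 52260880). The test counted each as a separate gene, so its p-value overstates the number of independent loci. Of 22 midbrain, hindbrain and spinal cord regulators, 1 was marked (adjusted p = 4.33e-06, Fisher's exact test): Mafb at 17.0 (15.8 and 18.6), which also stands in the subpallial list as a gene of interneurons. Atoh1, Egr2, En1 and En2 were unmarked. Of 20 genes of the diencephalon, which is itself a part of the forebrain, 4 were marked (adjusted p = 0.00471, Fisher's exact test). They were Tcf7l2 at 10.04 (13.3 and 5.96), Foxp2 at 8.91 (7.83 and 9.98), Lhx9 at 6.13 (5.90 and 6.69) and Otx2 at 3.37 (4.09 and 3.39). The diencephalon call was lost in the replicate 1 list, where 7 genes were marked, and in the pooled list.

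Cajal-Retzius and cortical hem genes, of the earliest cortical neurons and the dorsal midline, were marked in 4 of 14 cases (adjusted p = 0.0661, Fisher's exact test). Cxcr4 had 12.2 (12.8 and 7.36), Reln 6.90 (5.92 and 6.98), Lhx5 3.22 (3.86 and 3.03) and Ebf3 2.45, with no peak in replicate 1 and 2.98 in replicate 2. This list passed the threshold at a −log10 q of at least 5 and against a background without olfactory, vomeronasal and predicted genes.

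Lists of other cell types of the head were lower than other genes. Astrocyte and oligodendrocyte genes were marked in 4 of 15 cases (adjusted p = 0.0423, Fisher's exact test), with Aldoc at 9.07 (10.1 and 8.12) and Gfap at 5.61 (4.43 and 5.47), while Olig2 had 2.56 and no promoter peak in either replicate's list. None of 14 microglial genes was marked (adjusted p = 5.91e-05, Fisher's exact test), among them Aif1 and the complement genes C1qa, C1qb and C1qc; 1 gene was marked in each replicate's own list. Endothelial and pericyte genes (4 of 16) and meningeal and mesenchymal genes (4 of 16) each had an adjusted p of 0.0266 by Fisher's exact test. Their marked members had low enrichment, as in Cldn5, a tight junction gene of brain vessels, at 2.60 (3.07 and 2.55) and the collagen gene Col1a2 at 4.90 (5.09 and 4.47). Choroid plexus and ependymal genes were marked in 2 of 12 cases (adjusted p = 0.0208, Fisher's exact test), Foxj1 at 4.98 (7.15 and 3.36) and Enpp2 at 4.39 (5.32 and 3.49), and erythroid genes in 0 of 18 (adjusted p = 4.33e-06, Fisher's exact test), with 3 and 2 marked in the lists of replicates 1 and 2. The endothelial and meningeal calls were lost in each replicate's own list, in the pooled list and with promoters of 2.5 kb. The astrocyte and oligodendrocyte call was lost in the pooled list and at 2.5 kb, and the choroid plexus call in the replicate 1 list and at 2.5 kb.

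Genes of other organs were rarely marked. The counts were 1 of 18 for liver (adjusted p = 9.67e-05), 3 of 16 for heart (adjusted p = 0.00719), 1 of 14 for skeletal muscle (adjusted p = 0.000963), 3 of 16 for limb and craniofacial genes (adjusted p = 0.00719), 0 of 18 for endoderm, kidney and epithelium (adjusted p = 4.33e-06; 0 and 1 in the replicates' own lists) and 1 of 14 for pluripotency and germline genes (adjusted p = 0.000963), all by Fisher's exact test. The marked members with the largest values were Myh7, a cardiac myosin gene, at 15.7 (12.1 and 14.9), Mylpf, a muscle myosin light chain gene, at 15.2 (13.5 and 14.3) and Shh at 8.10 (7.23 and 7.03). The Mylpf peak (chromosome 7, 127208756 to 127210135) also covered a promoter of Tbc1d10b, and the peak of Foxa3, the marked liver gene, a promoter of Sympk. The germline gene Dazl had 6.60 (6.15 and 5.21). The heart call was lost with promoters of 2.5 kb. For the liver and heart lists, as for the astrocyte and choroid plexus lists, the marked count lay inside the central 95% of CpG-matched random lists.

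**Figure D3:**
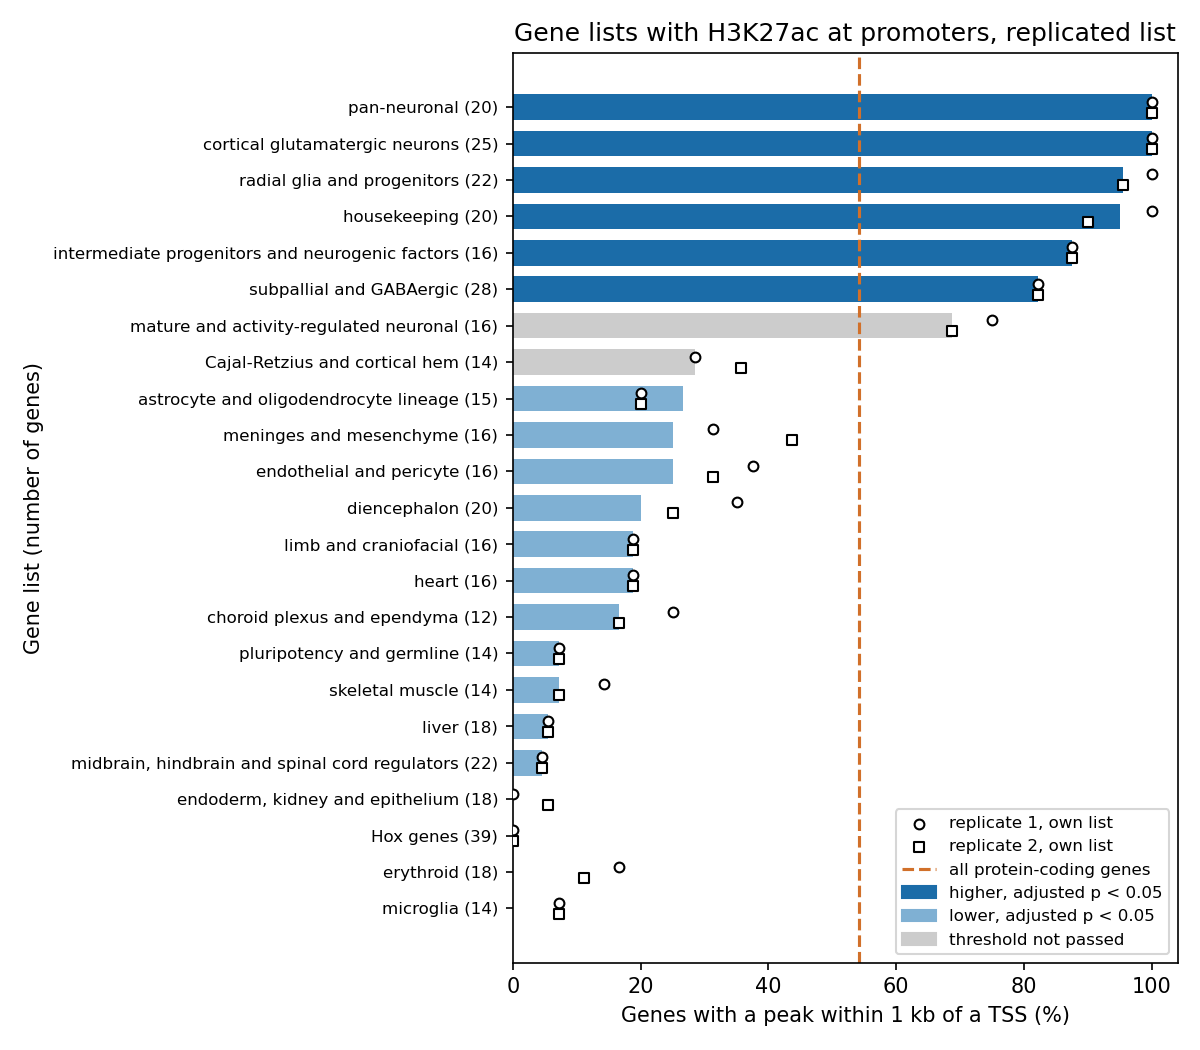
Share of genes with an H3K27ac peak within 1 kb of a TSS (%, horizontal axis) for each of the 23 gene lists (vertical axis, number of genes in parentheses); bars are the replicated list, open circles and squares each replicate's own list, and the dashed line all protein-coding genes (54.2%). Dark blue bars are lists with a higher and light blue bars lists with a lower share at an adjusted p under 0.05, and grey bars did not pass; cortical glutamatergic and pan-neuronal genes reached 100%, while Hox, erythroid, microglial and endoderm genes were at 0%.

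The fifth comparison counted distal peaks around the same genes. Genes of cortical glutamatergic neurons had a median of 10 distal peaks within 50 kb, against 2 in random lists with as many marked genes. Pan-neuronal genes had 8.5 (random 1.5), intermediate progenitor genes 7.5 (random 1.5), radial glia genes 5 (random 1.5) and subpallial and GABAergic genes 4.5 (random 1), each above the 99.9th percentile of 10000 random lists. Tcf4 had 87 distal peaks around its TSSs, Meis2 36, Myt1l 34, Foxp1 28, Map2 24 and Foxg1 15. Windows lay around every TSS, so long genes with many TSSs had more sequence searched. The random lists were not matched on gene length or number of TSSs. With a single window at the 5′ end of each gene, the glutamatergic, pan-neuronal, intermediate progenitor, radial glia and subpallial lists stood at the 99.4th percentile or above. In this setting promoters were also defined only at 5′ ends, so peaks at a gene's other TSSs could count as distal. It limits the sequence searched but cannot exclude a gain from genes with many TSSs. The midbrain, hindbrain and spinal cord, Hox, limb, endoderm, liver and pluripotency lists had a median of 0 distal peaks, as did their random lists, and housekeeping genes had 2 (random 1.5, 72.5th percentile).

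Of the 23 lists, 10 lay above the central 95% of random lists, 8 of them in each replicate's own list as well, and 0 below it. The other 5 besides those above were the Cajal-Retzius (median 2.5), mature neuronal (3), astrocyte and oligodendrocyte (2), microglial (1.5) and skeletal muscle (1.5) lists. They were above that range in 8, 6, 6, 7 and 10 of 11 settings, in the same order. The mature neuronal list was inside it in both replicates' own lists (91.0th and 95.8th percentiles), and the Cajal-Retzius list in that of replicate 2 (97.2nd). C1qa, C1qb and C1qc had 7, 6 and 6 distal peaks, and they lie side by side on chromosome 4 (136880129 to 136898803), so their windows overlap. Random lists without olfactory, vomeronasal and predicted genes, an alternative chosen after seeing the data, left 7 lists above that range, without the astrocyte and oligodendrocyte (95.3rd), microglial (96.6th) and skeletal muscle (95.1st) lists.

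The sixth comparison ranked regions of clustered distal peaks. Joining gave 19523 domains, of which the top 20 held 6.37% of the summed enrichment times width. The first domain spanned 84.2 kb on chromosome 7 (79496173 to 79580325) with 10 peaks, and its nearest protein-coding TSS was that of Rhcg, 14604 bp away. The next spanned 51.4 kb on chromosome 13 (83712285 to 83763731), 59397 bp from Mef2c. The others among the first 5 lay on chromosome 2 (30591094 to 30809856, 48 peaks, covering TSSs of 1700001O22Rik, Cstad and Ntmt1), on chromosome 3 (88177149 to 88243905, 8897 bp from Mef2d) and on chromosome 15 (85610627 to 85710354, 24629 bp from Ppara). Domains at Sox2 (chromosome 3, 34629717 to 34692679) and near Myt1l (chromosome 12, 29627744 to 29772896, 61044 bp away), genes of neural progenitors and neurons, ranked 16 and 18.

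The other domains of the top 20 had as nearest genes Sorl1, Dscaml1, Gse1, Ncor2, Irf2bpl, Gm26897, Lrrc74a, Foxo6, Msra, Gm49450 with Tuba1a, Sdccag8, Ttc28 and Kif13b. The nearest gene is a position on the map and not a measured target. In the replicates' own lists, ranked in the same way, 16 of the 20 domains in the replicate 1 list and 17 in the replicate 2 list overlapped a top 20 domain. Ranking by covered length kept 12 of the 20. Leaving out peaks near the TSSs of non-coding genes too, an alternative chosen after seeing the data, kept 9. The domains nearest to Rhcg, Mef2c and Mef2d and the domain at Sox2 were among those no longer in the top 20.

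The seventh comparison counted short sequence words in 41878 windows at distal peaks against 67946 flanking windows. The octamer ATGCAAAT, bound by POU factors, exceeded words of its composition by 0.78 ± 0.24 on the log2 scale (SD over 20 chromosomes). The homeodomain word TAATTA exceeded its composition by 0.59 ± 0.12 and the nuclear factor I half-site word TTGGCA by 0.53 ± 0.10. The E-box words CAGCTG and CAGATG, bound by basic helix-loop-helix factors, stood at 0.33 ± 0.12 and 0.23 ± 0.08. These 5 words were above 0 on 20 of 20 chromosomes, in the replicated list and in each replicate's own list. Before the median of their composition was subtracted, log2 ratios in the replicated list were 0.55 (ATGCAAAT), 0.15 (TAATTA), 0.58 (TTGGCA), 0.76 (CAGCTG) and 0.32 (CAGATG). Most of the value of TAATTA thus came from the subtraction.

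Among words of the same composition, ATGCAAAT stood at the 98.7th percentile of 840 words and TTGGCA at the 95.6th of 180, but CAGCTG only at the 86.3rd of 102 and CAGATG at the 78.3rd of 180, and TAATTA had only 14 words to compare with. CCGCCATC, a YY1 word, stood at the 95.5th of 336 and CTATTTATAG, a MEF2 word, at the 94.3rd of 5040. The SOX word ACAATG stood at 0.06 ± 0.09 (above 0 on 16 chromosomes), the AP-1 word TGACTCA at −0.08 ± 0.11 (8 chromosomes) and the GATA word GATAAG at −0.04 ± 0.10 (6 chromosomes), all within their spread of 0. CTATTTATAG, with 101 occurrences in peaks, stood at 0.76 ± 0.83, and CCGCCATC, with 291, at 0.45 ± 0.76, above 0 on 15 and 16 chromosomes. Chromosomes are not biological replicates, and no p-value is given.

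**Figure D4:**
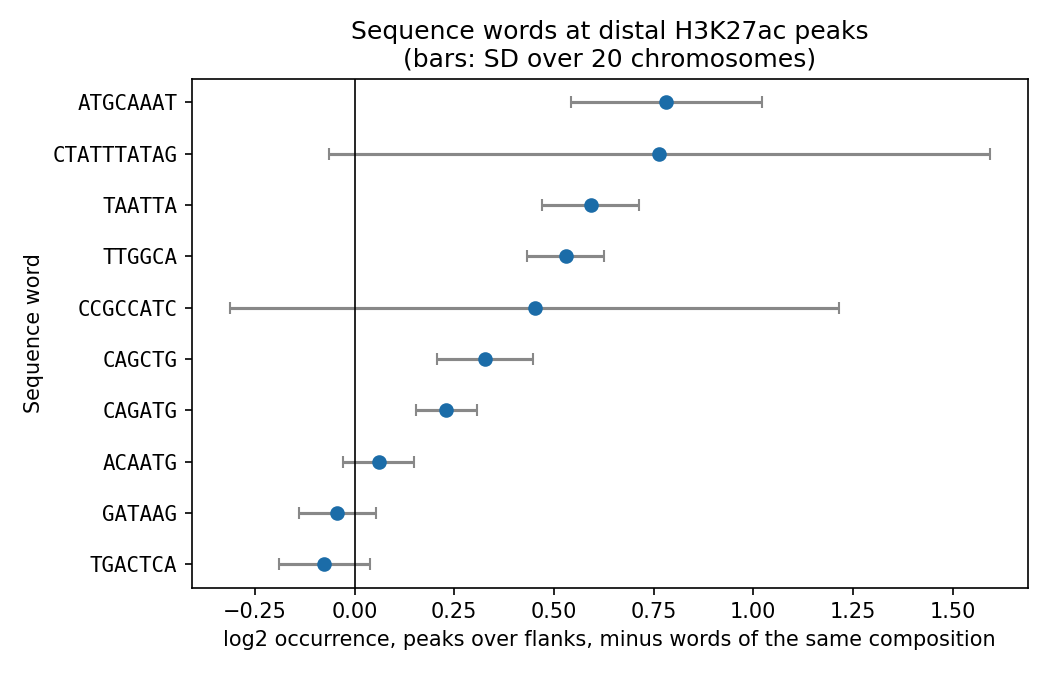
Occurrence of 10 sequence words (vertical axis) in 500 bp at distal peaks over flanking windows, as log2 ratio minus the median of words of the same length and composition (horizontal axis); points are the replicated list and bars the SD over 20 chromosomes. ATGCAAAT, TAATTA, TTGGCA, CAGCTG and CAGATG lie above 0 by more than the SD, from 0.23 to 0.78, and the bars of the other 5 words cross 0.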

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

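Sequence outside the assembled chromosomes entered no comparison with genes, domains or words, and it carried 10 replicated peaks. The strongest lay on an unlocalized scaffold of chromosome 4 (15497 to 17522 of the scaffold) with an enrichment of 53.4, against 51.9 and 39.1 in replicates 1 and 2, and ranked 31 among all replicated peaks. It covered the TSS of a predicted protein-coding gene without an assigned symbol. The next strongest, on an unlocalized scaffold of chromosome X (110879 to 111730), had 13.1. No biological explanation was tested for these peaks.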

How the results depend on the processing

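Peak sharing moved with every choice tried, and the causes were not tested beyond what each choice does by construction. The shared shares of replicate 1 and replicate 2 were 65.1% and 71.5% at an overlap of 1 bp, 42.7% and 46.4% at 50% of both peaks, 62.3% and 69.7% at a −log10 q of at least 2, 75.8% and 81.5% at 5, 62.7% and 64.1% with lists of equal length, and 85.4% and 86.5% among the 20000 peaks with the largest −log10 p. Spearman's rho was, in the same order, 0.671, 0.821, 0.714, 0.762, 0.705 and 0.787. The share of pooled peaks found in both replicates was 49.7% at 1 bp and 32.9% at 50% of both. The promoter share was 24.9% with promoters of 0.5 kb, 31.1% with 2.5 kb, 20.3% with the 5′ end of each gene, 29.4% at a −log10 q of at least 5, 19.04% in the pooled list, and 21.2% to 22.5% in the replicates' own lists. The number of gene lists past the promoter threshold was 16 to 22 over 9 alternatives, each call keeping its direction. Of the 207 tests of single lists under these alternatives, 15 lost and 2 gained their call. The number of lists above the central 95% of random lists for distal peaks was 6 with the 5′ end of each gene and 7 to 11 otherwise; the glutamatergic, pan-neuronal, intermediate progenitor, radial glia and subpallial lists stayed above it in all 11 settings. Of the top 20 domains, 12 were found again when ranked by covered length, 9 with non-coding TSSs left out (chosen after seeing the data), and 16 to 20 otherwise. The same 5 words were above 0 on all 20 chromosomes under each alternative. Depth was unknown, so it was not possible to say how far weak peaks were limited by it. No paired analysis was possible because the labels give a single group.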

Other observations

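The tests below on vascular and mesenchymal genes, on silent gene families, on the CpG-matched range of 5 lists and on neural against other microRNA genes were chosen only after the related results were seen; the others were set before their results were seen.

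MicroRNA genes were in no comparison above. Of 20 microRNA genes known from neural tissue, 16 had a replicated peak within 1 kb. All copies of Mir9 (Mir9-1, Mir9-2 and Mir9-3, with peaks of 32.8, 22.5 and 25.9) and of Mir124 (Mir124a-1, Mir124a-2 and Mir124a-3, with 37.3, 16.8 and 32.2) had one, as did Mir125b-1 (38.5), Mir137 (11.8) and Mir132 (6.68), each in both replicates' own lists. Mir128-1, Mir138-1, Mir218-1 and Mir219a-2 had none. Of 25 microRNA genes known from other tissues, among them muscle, liver and blood, only Mir208b, inside Myh7, had a replicated peak (10.5). The neural list was written after 7 of its members had been seen in the largest domains, so the 10 genes of their 4 families were left out of the test. A hypothesis was that neural microRNA genes carry the mark more often: of the other 10, 6 had a peak, against 1 of 25 (p = 0.000799, two-sided Fisher's exact test), and 5 of 9 against 1 of 20 when genes within 10 kb counted as 1 locus (p = 0.00548, Fisher's exact test). The peak at Mir219a-1 also covered promoters of Ring1 and H2-Ke6.

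The largest distal domains held microRNA genes: 10 of the top 20 did, among them the domains of Mir9-3 (rank 1), Mir9-2 (rank 2), Mir9-1 (rank 4), Mirlet7b with Mirlet7c-2 (rank 5), Mir125b-1 (rank 6) and Mir124a-1 (rank 20). Long domains hold more genes of any kind, but 0% of 10000 sets of other domains of like span had as many, with a mean of 1.57 and a highest count of 7. Once peaks within 1 kb of any annotated gene's TSS were left out, 3 of the 10 still overlapped a top 20 domain. The annotated genes included the microRNA genes themselves, so peaks at their starts were removed by construction. The drop therefore cannot tell promoters of non-coding genes counted as distal from acetylation at the microRNA genes. That explanation stays open, and the pattern was found and tested on the same data.

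Promoter marks differed between the gene lists in ways that technical features could produce. CpG content was measured only around the 5′ end of each gene, while a peak at any TSS made a gene marked. Measured there, it did not account for 16 of the 21 lists past the threshold. Their marked counts lay outside the central 95% of 10000 CpG-matched random lists. CpG content at other promoters of the same genes was not matched. In the other 5 lists (subpallial, astrocyte and oligodendrocyte, choroid plexus, liver and heart) CpG content stays open. Silent gene families in the background are argued against for the lists with a higher share, since 6 of 6 kept their call without them; their removal raises the background share, so the lower lists could not lose theirs. A low share of their cells in the tissue stays untested for the vascular and mesenchymal lists: their 8 marked genes had a median enrichment of 3.09 against 11.4 over all marked genes, but the 8 other marked genes of the liver, heart, skeletal muscle, limb, endoderm and germline lists had a median of 5.23, also below that level, with single genes as high as Myh7 (15.7) and Mylpf (15.2). The peaks of Mylpf and of Foxa3, another of these organ genes, also covered promoters of Tbc1d10b and Sympk, respectively. The design has a single tissue, so no biological explanation was tested.

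Chromosome X had a higher shared share than the autosomes, with 69.6% of 1406 replicate 1 peaks (interval 67.2 to 72.0) against 59.5% over the autosomes together and 57.6% to 61.2% on single autosomes. Autosomal peaks in the same deciles of enrichment shared 69.5%. In replicate 2 the values were 75.7% (interval 73.3 to 78.0), 65.7% and 72.2%. Promoters held 40.04% of the X peaks of replicate 1 and 20.9% of its autosomal peaks.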
